A study of Mus musculus with 8 samples.

How the data were processed

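RNA of mouse bone marrow-derived macrophages was measured on 8 single-colour Illumina bead arrays, 4 from wells given rat IAPP and 4 from wells given human IAPP. Per the labels, cells were grown from C57BL/6 bone marrow for 7 days in medium with 15% L929-conditioned medium, a source of macrophage growth factor, and the culture medium held 10% serum. Cells were then plated in 24-well plates, kept without the conditioned medium for 12 hours and exposed to peptide for 12 hours. Total RNA was extracted with a column kit, checked on a Bioanalyzer and converted to biotinylated cRNA with the MessageAmp kit, per the labels' protocols. Groups and replicate numbers were taken from the sample descriptions.

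The authors deposited a table of probe intensity values on a linear scale, not normalised between arrays, with a detection p-value beside each signal, per the file headers. Signals were not background subtracted: undetected probes lay near a median of 289 to 349 units per array. The detection p-value ranks a probe among the negative control beads of its array. Scanner, its software and the summary of beads are not given in the sources used here, nor is the slide of each array. A second deposited table holds rescaled intensity values, each column a straight line of the same array's signal (Pearson r of at least 0.999999 across probes). Their scale is linear, they are not centred, and their upper quartiles lie between 717 and 727. Column medians are 352.6, 356.6, 353.8 and 361.1 for rat replicates 1 to 4 and 361.8, 362.9, 359.2 and 367.7 for human replicates 1 to 4. The method behind them is not stated, and they were used only as an alternative. All per-sample columns were used.

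Background was corrected with limma 3.58.1 in R 4.3.3 by normexp, with negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalisation between arrays and log2. This offset pulls the differences of dim probes towards 0. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, 11451 of 25697. Probes were named through the platform annotation, with symbols updated by gene number in a RefSeq table of assembly GRCm38.p6 that matched 23962 probes. That annotation gives 1 symbol for 23978 probes, several for 0, and leaves 1719 unlisted. The array table names no genome build, so no coordinates are given. A gene was represented by its brightest tested probe, giving 7809 genes.

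Human minus rat IAPP was fitted with lmFit and eBayes without covariates, with Benjamini-Hochberg adjustment over the probes or genes tested and a threshold of 0.05. Of the 33 gene and marker lists, fixed before the data were examined, 28 had at least 5 measured members. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. A call in a list adjusted over the list alone uses only its members. Where a probe was undetected on all 4 arrays of a group, the fold is a bound: the brighter group's mean against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes. Signals of at least 60000 on all 4 arrays of a group were treated as near the scanner ceiling and their fold is also a bound. Folds of dim genes depend on the background correction, and values that keep the background give smaller ones.

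Genes were named by a rule fixed beforehand. It takes the 12 largest rises and 12 largest falls, by fitted difference, among called genes whose groups do not overlap. It adds up to 3 members with the smallest p of each called list and up to 2 of each other list, and the called members of lists for other cell types. It always includes Il1b, Il1a, Tnf, Il6, Il1rn, Nlrp3, Casp1, Pycard, Ccl2, Tlr2, Cd36 and Iapp.

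Alternatives covered no background correction, normexp with an offset of 50, median scaling, cyclic loess, the authors' rescaled values, 3 other filters on dim probes, a variance trend with a robust prior, array weights, replicate number as a block, each array left out, the mean over probes, other thresholds, and camera with an estimated correlation or fry. No pair of arrays held identical values, and the smallest SD of the log2 difference between 2 arrays was 0.214.

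The steps were tested on simulated arrays of the comparison of human against rat IAPP, with 200 changed probes among 11874 tested. The changed probes were drawn from those of middle brightness on the rat arrays. The recovery rates below therefore do not cover dim or very bright probes. With noise as measured, 50.8% of probes changed by 0.5 on the log2 scale were recovered, 98.5% of those changed by 1 and 100% of those changed by 2. Of 177 calls 6.21% were false, slightly above the threshold of 5% set by the adjustment. With the background noise added again, 12936 probes were tested, 29.9%, 91.0% and 100% were recovered and 8.70% of 161 calls were false. A list shifted by 0.5 was called and 0 of 20 unshifted lists were. The simulation changed far fewer probes than the 6234 of 11451 called in the data, so it does not show how normalisation behaves with so many changes. Its noise was independent between probes, and the list shift was added after normalisation. The list result therefore does not cover lists of correlated genes.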

Results

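Transcript levels were measured on 8 Illumina mouse expression arrays, each hybridised with RNA from a separate culture well of bone marrow-derived macrophages of C57BL/6 mice. Islet amyloid polypeptide (IAPP, amylin) is a hormone that pancreatic beta cells release together with insulin. The human peptide aggregates into amyloid, whereas the rat peptide differs in sequence and does not readily form fibrils, which makes it the control here. The comparison asks how macrophage gene expression at 12 hours differed between wells given the aggregating peptide and wells given the control peptide. No untreated wells are among the samples, so rises and falls below are relative to rat IAPP. Effects of aggregation and of the difference in sequence cannot be told apart. Rat IAPP was given to 4 wells and human IAPP to 4 wells. The dose was 15 µM per the sample titles and the design text, while the treatment protocol in the labels gives the same figure in millimolar. The sample labels used here mark no separate experiments or animals among the 8 wells. The p-values therefore measure the spread between wells, which may be technical. Mean raw signal ran from 1523 to 1967 intensity units on rat arrays 1 to 3, was 1180 on rat array 4, and ran from 1144 to 1368 on the human arrays. Between 42.1% and 47.6% of the 25697 probes were detected per array, and the number of arrays limits the precision.

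Il1rn, which encodes the interleukin-1 receptor antagonist, rose 84.7-fold with human IAPP, a log2 difference of 6.40 (SE 0.10, n = 4 per group, adjusted p = 2.9e-10). The monocyte-attracting chemokine genes Ccl7 and Ccl2 rose 52.8-fold and at least 27.3-fold. Edn1, the endothelin precursor gene, rose at least 27.8-fold, and Inhba, which encodes a subunit of activin, rose 42.0-fold. The polo-like kinase gene Plk2 rose 43.8-fold and the urokinase gene Plau by a log2 difference of at least 4.52. The growth-responsive transcription factor genes Egr2 and Egr1 rose 22.9-fold and 19.0-fold. Tnfrsf12a, the receptor gene for the cytokine TWEAK, rose by a log2 difference of 4.39, Rgs1, a brake on G protein signalling, 18.9-fold (31.1-fold and 37.3-fold on other probes), and the chondroitin sulfotransferase gene Chst11 at least 13.7-fold. Among these 12 genes the SE of the log2 difference lay between 0.065 for Egr2 and 0.20 for Ccl7. All 4 human wells lay above all 4 rat wells, as the naming rule required. The chosen probe of Ccl4 lay near the scanner ceiling with human IAPP. Its log2 difference of 4.22 is thus a bound and fell just under that of Rgs1 (4.24), while a second Ccl4 probe gave 6.15. The words at least mark a gene undetected on all 4 arrays of its dimmer group, where only a bound on the fold can be given. A second Il1rn probe, undetected with rat IAPP, rose at least 9.45-fold.

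Among the falls, Angptl4, an inhibitor of lipoprotein lipase, fell by 3.66 on the log2 scale (SE 0.16, n = 4 per group, adjusted p = 1.7e-07), which is 12.6-fold. Acot1, an acyl-CoA thioesterase gene, was 7.95-fold lower (2.89-fold on a second probe), and Abcd2, a peroxisomal fatty acid transporter gene, at least 3.10-fold lower. Hpgd, which encodes the main prostaglandin-degrading dehydrogenase, was 11.3-fold lower. The pro-apoptotic gene Bmf was at least 5.38-fold lower and Trp53inp1, a gene induced by p53, was 5.33-fold lower. The other genes of this set were Slc46a3 (9.54-fold), Gpr34 (at least 4.54-fold), Mtus1 (7.59-fold), Kctd12b (6.33-fold, detected on 2 of 4 human arrays), Fgd2 (5.87-fold, detected on 1 of 4) and Il15 (5.54-fold), which encodes a cytokine that sustains lymphocytes. The 4 human wells lay below the 4 rat wells for each of these 12 genes, again as the naming rule required. Probes for Acot1, Hspd1 and ribosomal protein genes can share sequence with near-identical copies, so their values may include related transcripts.

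**Figure D1:**
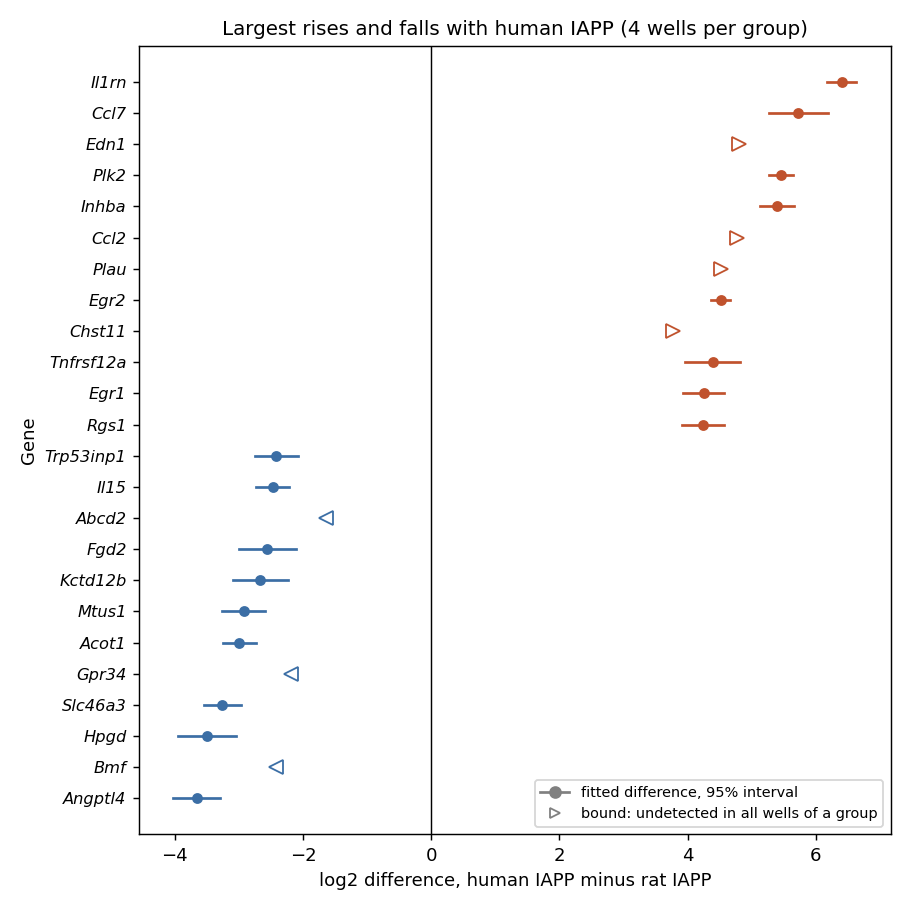
Log2 difference between human and rat IAPP (horizontal axis) for the 12 largest rises and the 12 largest falls by fitted difference (vertical axis), with 4 wells per group. Ccl4, whose chosen probe lay near the scanner ceiling, is not among them at 4.22 but gave 6.15 on a second probe. Filled points are fitted differences with their 95% intervals, and open triangles are bounds for genes undetected on all 4 arrays of a group; Il1rn stands at 6.40 and Angptl4 at -3.66.

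Folds and bounds hold with the background correction used, and those of dim genes were much smaller in some alternatives, such as values that keep the background. The smallest log2 differences over all alternatives were 5.09 for Il1rn, 4.14 for Plk2, 3.96 for Rgs1, 3.78 for Egr1, 3.67 for Ccl7, 3.12 for Inhba and Egr2, 2.77 for Edn1, 2.66 for Ccl2, 2.56 for Tnfrsf12a, 2.44 for Plau and 1.91 for Chst11. Among the falls they were -2.56 for Slc46a3, -2.04 for Acot1, -2.03 for Hpgd, -1.96 for Angptl4, -1.93 for Il15, -1.75 for Mtus1, -1.71 for Trp53inp1, -1.24 for Bmf, -0.99 for Gpr34, -0.95 for Kctd12b, -0.91 for Fgd2 and -0.74 for Abcd2. Among genes given with their lists, the largest such reductions were to 1.27 for Bcl2, 1.19 for Csf1, 0.63 for Dcstamp, 1.86 for Il1a, 2.27 for Ccnd1 and, lower with human IAPP, -0.74 for Sgsh and -0.41 for Mmp8.

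Of 7809 genes tested, 4401 differed between the groups at the chosen threshold (limma, Benjamini-Hochberg), 1860 higher and 2541 lower with human IAPP. Changes of at least 1.5-fold were found for 950 higher and 1164 lower genes. At 4-fold or more, rises outnumbered falls, with 108 genes higher and 25 lower. At probe level, 6234 of 11451 probes were called, 2811 higher and 3423 lower. The groups did not overlap for 4007 genes, 51.3% of those tested, where chance gives 2.86%. Without rat replicate 4, which stood apart from the other rat arrays, 4758 genes and 6727 probes were called. The share of higher genes among the calls was 42.3%, but 16.98% when arrays were scaled to a common median, which moved the median of all genes to -0.35, and 53.5% with the authors' rescaled values. Of the 2117 genes with more than 1 tested probe, 31 had called probes in opposite directions, none of them named here.

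The interleukin-1 axis moved unevenly. Il1a rose 8.72-fold (log2 difference 3.12, SE 0.24, adjusted p = 6.0e-06), and its antagonist gene Il1rn rose 84.7-fold. Il1b was already bright with rat IAPP, at a log2 intensity of 14.33 ± 0.11 (SD, n = 4), and reached 14.65 ± 0.23 (SD, n = 4) with human IAPP, a 1.24-fold difference with overlapping wells (adjusted p = 0.045). Of the inflammasome and IL-1 processing genes, 5 of 17 were higher and 9 lower, and 15 passed adjusted over the list alone. Nlrp3, the sensor gene, rose 3.16-fold (SE 0.19 on the log2 scale), while Pycard, the adaptor gene, fell by 0.97 on the log2 scale (SE 0.10) and Casp1, the protease gene, fell by 0.47 (SE 0.08). The Casp1 difference shrank to -0.18 in an alternative, and its call was lost against rat replicate 4 alone (-0.37, adjusted p = 0.073), a setting added after seeing the data. Txnip, which encodes a thioredoxin-binding protein, fell by 1.60 (SE 0.12). The median of the list was -0.42 and the list was not called (camera adjusted p = 0.28). The Il1b call was lost on leaving out rat replicate 2, 3 or 4 or human replicate 2, 3 or 4, with adjusted p from 0.065 to 0.12, and its adjusted p was 0.092 with replicate number as a block and 0.29 with median scaling.

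**Figure D2:**
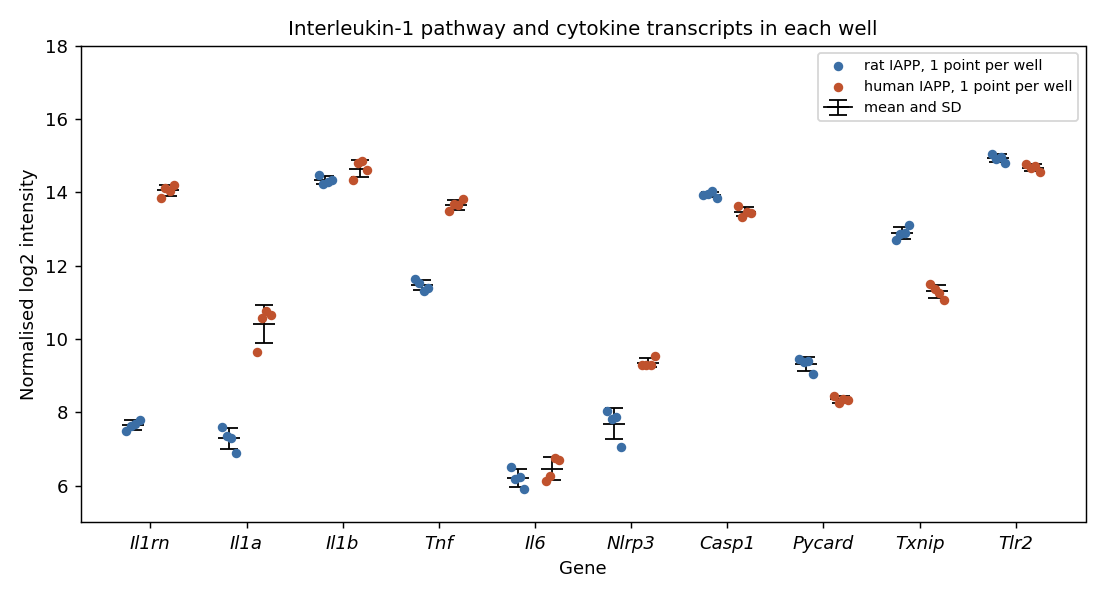
Normalised log2 intensity (vertical axis) of 10 genes (horizontal axis) in each of 4 rat IAPP wells and 4 human IAPP wells, with the mean and SD of each group. Il1b wells overlap between the groups at means of 14.33 and 14.65, whereas Il1rn goes from 7.65 to 14.05.

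Among inflammatory cytokines 9 of 13 rose and 2 fell, with a median log2 difference of 1.32 (1.204 with bounded genes at their bound), and 11 passed adjusted over the list alone. Osm, encoding oncostatin M, rose 9.29-fold, Csf1, the macrophage growth factor gene, 8.97-fold (detected on 1 of 4 rat arrays), and Tnf 4.56-fold, with SEs from 0.089 to 0.12 on the log2 scale and adjusted p of at most 1.8e-07. Il6 lay at the edge of detection (log2 difference 0.26, SE 0.17, adjusted p = 0.23). Of the chemokines, 9 of 16 rose and 2 fell, with a median of 0.62 and 11 genes passing adjusted over the list alone. Besides Ccl2 and Ccl7, the macrophage inflammatory protein genes Ccl3 and Ccl4 rose at least 10.5-fold and at least 18.6-fold, where the signal of all 4 human arrays lay near the scanner ceiling. A second Ccl4 probe, below the ceiling, gave 71.0-fold. NF-kB targets and feedback genes rose in 15 of 25 cases and fell in 4, with a median of 0.42 and 21 passing adjusted over the list alone. Besides Plau these included Bcl2l1, a survival gene, at 7.32-fold, and Gadd45b, a stress-response gene, at 3.65-fold. The camera adjusted p was 0.0044 for cytokines, 0.0031 for chemokines and 0.0029 for NF-kB genes; with an estimated correlation the adjusted p = 0.16, 0.12 and 0.12, so none of these calls was kept. When only probes detected on all 8 arrays were tested, which removes genes undetected with rat IAPP, the cytokine and chemokine calls were lost (adjusted p = 0.13 and 0.054).

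Of 39 measured genes of the type I interferon response, 32 were higher, 1 was lower and 6 did not pass, with a median log2 difference of 0.71 and 33 passing adjusted over the list alone. Rsad2, the viperin gene, rose 6.48-fold (log2 difference 2.70, SE 0.091), Usp18, a brake on interferon signalling, 3.56-fold (SE 0.070) and Cmpk2 3.36-fold (SE 0.099), with adjusted p of at most 8.5e-07. The list was called (camera adjusted p = 1.2e-09; adjusted p = 0.089 with an estimated correlation).

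Immediate early genes are those first induced by growth and stress signals, and many encode transcription factors. They were higher in 13 of 14 cases and lower in 1, all 14 passing adjusted over the list alone. Their median was 1.296, or 1.13 with bounded genes at their bound. Besides Egr1 and Egr2, Atf3 rose 4.38-fold (log2 difference 2.13, SE 0.082, adjusted p = 7.3e-08). This was the only list called both by camera with the preset correlation (adjusted p = 6.4e-07) and with an estimated correlation (adjusted p = 0.045).

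Of the cell cycle genes, 9 of 26 were higher and 3 lower, with 12 passing adjusted over the list alone. The cyclin gene Ccnd1 rose 11.2-fold (SE 0.11 on the log2 scale), the replication licensing factor gene Cdt1 4.80-fold (SE 0.12) and the chromatin assembly gene Chaf1b 2.36-fold (SE 0.11), all linked to entry into or passage through DNA replication. Other Ccnd1 probes gave 13.4-fold and 4.91-fold. The list median was 0.11 and turned to -0.27 with median scaling, a setting that also lowered the median of all genes. Its call was marginal (camera adjusted p = 0.047; adjusted p = 0.34 with an estimated correlation) and was lost without rat replicate 3 (0.052), rat replicate 4 (0.060) or human replicate 3 (0.105), and in most other normalisations and filters. The p53 and apoptosis genes went both ways, 7 of 22 higher and 11 lower, with 18 passing adjusted over the list alone. Plk2 and the survival gene Bcl2 (8.61-fold higher, SE 0.088) were among the rises, and the list was not called (camera adjusted p = 0.78), its median being -0.15 and its mean 0.057.

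In the unfolded protein and integrated stress response list 15 of 31 genes rose and 6 fell, 22 passing adjusted over the list alone, with a median of 0.37 that was -0.0024 with median scaling. Among its rises were Atf3, Ppp1r15a (4.23-fold, SE 0.079), whose product reverses the translation block of this response, and Chac1 (3.50-fold, SE 0.078), a glutathione-degrading enzyme gene. The list was called (camera adjusted p = 0.023; adjusted p = 0.23 with an estimated correlation). Heat shock genes rose in 8 of 12 cases with none lower, 8 passing adjusted over the list alone, with a median of 0.51 (camera adjusted p = 0.013; adjusted p = 0.23 with an estimated correlation). Among them the chaperone genes Hspd1, Ahsa1 and Stip1 rose 1.63-fold, 1.54-fold and 1.51-fold, calls that median scaling ended (adjusted p = 0.067, 0.22 and 0.22). NRF2 and oxidative stress genes split into 5 higher and 9 lower of 22, with 14 passing adjusted over the list alone, and the list was not called (camera adjusted p = 0.78, median 0.062). Srxn1 and Hmox1, both induced by oxidants, were 1.78-fold and 1.76-fold higher (SE 0.075 and 0.083).

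Genes of cholesterol biosynthesis were higher in 13 of 16 cases and lower in 1, with 14 passing adjusted over the list alone and a median of 0.76. The enzyme genes Hsd17b7, Cyp51 and Fdps rose 3.59-fold, 3.02-fold and 2.24-fold (SE 0.096, 0.082 and 0.067 on the log2 scale). The list was called (camera adjusted p = 6.3e-05; adjusted p = 0.089 with an estimated correlation). Glycolysis and hypoxia genes rose in 11 of 23 cases and fell in 2, 13 passing adjusted over the list alone, with a median of 0.21 (camera adjusted p = 0.013; adjusted p = 0.30 with an estimated correlation). The phosphofructokinase gene Pfkp, the hexokinase gene Hk3 and the glucose transporter gene Slc2a1 rose 2.59-fold, 2.29-fold and 2.19-fold (SE 0.12, 0.080 and 0.070). LXR, PPAR and lipid handling genes gave 6 higher and 8 lower of 19, 14 passing adjusted over the list alone, with Angptl4 lower and Pparg, a lipid-sensing nuclear receptor gene, 2.42-fold higher (SE 0.081). That list was not called (camera adjusted p = 0.78, median -0.18).

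Ribosomal protein genes were the only list called lower: 10 of 18 fell and none rose, 10 passing adjusted over the list alone, with a median of -0.31. Rps15, Rps3 and Rpl19 fell by 0.51, 0.49 and 0.39 on the log2 scale (SE 0.078, 0.085 and 0.068), and the Rps3 call was lost with the authors' rescaled values (adjusted p = 0.073) and against rat replicate 4 alone (0.051). The list call (camera adjusted p = 0.034; adjusted p = 0.44 with an estimated correlation) was lost without rat replicate 4 (0.055) or human replicate 2 (0.058), with median scaling (0.63) and with the authors' values (0.67, median -0.026). Oxidative phosphorylation genes were lower in 12 of 28 cases and higher in 1, with 12 passing adjusted over the list alone, and the list was not called (camera adjusted p = 0.22). Its median of -0.17 turned to 0.060 with the authors' values. Cox5a fell by 0.40 (SE 0.070), a call lost with median scaling (log2 difference -0.46, adjusted p = 0.051) and with the authors' values (-0.071, adjusted p = 0.35), and Atp5g1 rose 1.35-fold (SE 0.082), a call lost with median scaling (0.31) and against rat replicate 4 alone (0.066).

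Classical activation effectors were higher in 15 of 20 cases and lower in 2, with 17 passing adjusted over the list alone and a median of 1.299 (camera adjusted p = 1.6e-06; adjusted p = 0.16 with an estimated correlation). Edn1, Inhba and the urokinase receptor gene Plaur (5.18-fold, SE 0.076) were among the rises. Alternative activation genes gave 6 higher and 4 lower of 14, 10 passing adjusted over the list alone, with Egr2 and the transglutaminase gene Tgm2 (2.20-fold higher, SE 0.073) among the rises and Arg1, named after its value was seen, 3.48-fold lower, with a median of 0.072 and no call (camera adjusted p = 0.34). Negative regulators of inflammation were 7 higher and 5 lower of 15, 12 passing adjusted over the list alone, with a median of 0.17 and no call (camera adjusted p = 0.23). Besides Il1rn, the MAP kinase phosphatase gene Dusp1 rose 4.55-fold (SE 0.074). Antigen presentation and costimulation genes were 9 higher and 4 lower of 21, 13 passing adjusted over the list alone, without a call (camera adjusted p = 0.14, median 0.16). The class Ib molecule gene H2-M2 rose 7.94-fold (SE 0.089) and the costimulatory receptor gene Cd40 3.00-fold (SE 0.097), with 3.59-fold and, on a dimmer probe, 1.28-fold on other probes.

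**Figure D3:**
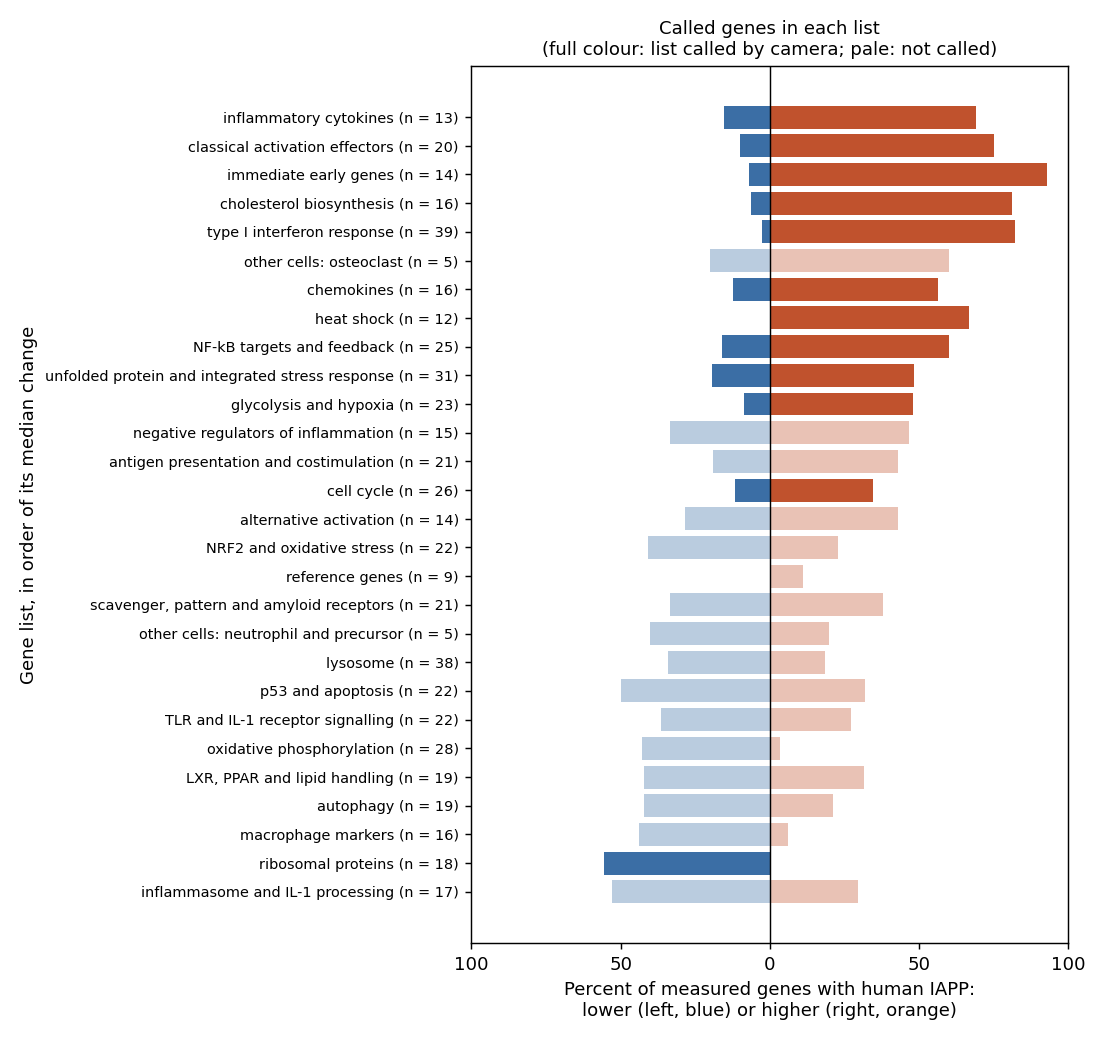
Percent of the measured genes of each list (vertical axis, number measured in parentheses) that were called lower (left) or higher (right) with human IAPP (horizontal axis, percent). Full colour marks the 12 lists called by camera with the preset correlation, of which ribosomal proteins alone were lower.

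Receptor genes changed in both directions. Of 22 TLR and IL-1 receptor signalling genes 6 were higher and 8 lower, 14 passing adjusted over the list alone, with a median of -0.16 and no call (camera adjusted p = 0.78). Tlr8, an endosomal RNA receptor gene, fell by 2.30 (SE 0.10), Cd180 rose 4.50-fold (SE 0.080), and Tlr2 was lower by a log2 difference of -0.26 (SE 0.083, adjusted p = 0.024) that turned to 0.076 with the authors' rescaled values. The Tlr2 call was also lost with median scaling (log2 difference -0.30, adjusted p = 0.22), cyclic loess (0.084) and without rat replicate 1 or 3 or human replicate 2 or 4. Scavenger, pattern and amyloid receptor genes were 8 higher and 7 lower of 21, 15 passing adjusted over the list alone, and the list was not called (camera adjusted p = 0.75, median -0.047, mean 0.082). Clec4e, the Mincle gene, rose 2.65-fold (SE 0.081) and Trem3 2.01-fold (SE 0.099), while the single probe of the scavenger receptor gene Cd36 was undetected on all 8 arrays, as was that of mouse Iapp. Lysosome genes were 7 higher and 13 lower of 38, 20 passing adjusted over the list alone, with no call (camera adjusted p = 0.65). Their median of -0.090 turned to 0.11 with the authors' values. Sgsh fell by 1.86 (SE 0.19) and the proton pump subunit gene Atp6v1h rose 2.22-fold (SE 0.074). Autophagy genes were 4 higher and 8 lower of 19, 13 passing adjusted over the list alone, with no call (camera adjusted p = 0.35, median -0.19). The kinase genes Ulk1 and Pik3c3, which act early in autophagosome formation, fell by 1.24 (SE 0.091) and 0.70 (SE 0.069).

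Of 16 macrophage markers 7 were lower, 1 was higher and 8 did not pass, with 8 passing adjusted over the list alone and no call (camera adjusted p = 0.087, median -0.27). Mertk, a receptor for apoptotic cells, fell by 1.18 (SE 0.12) and Cd14, the lipopolysaccharide co-receptor gene, rose 1.53-fold (SE 0.066). Osteoclast markers were 3 higher and 1 lower of 5, and the list was not called (camera adjusted p = 0.25). Dcstamp, a cell fusion gene, was at least 3.49-fold higher, Tcirg1 1.64-fold and Ctsk 1.62-fold higher, and Nfatc1 2.39-fold lower. Other Nfatc1 probes were 2.03-fold and 1.99-fold lower and 1.15-fold higher, the last not passing. Neutrophil and precursor markers were 1 higher and 2 lower of 5 (camera adjusted p = 0.68). Among them were Mmp8 at -1.46 (SE 0.20) and Elane at 0.44 (SE 0.17), the last a dim gene whose call was lost in most alternatives. Csf3r was at -0.99 (SE 0.11). Other Csf3r probes gave -0.82 and -0.41, which passed, and -0.17 and 0.096, which did not. Of 4 measured stromal markers, Acta2, the smooth muscle actin gene, fell by 0.80 (SE 0.17). Other Acta2 probes gave -0.73 (adjusted p = 0.013), -0.74 (0.10) and -0.28 (0.33). In normalised values all 4 markers were highest in rat replicate 4, with a median 1.19 above the other rat arrays. In raw signal, where that array was the dimmest rat array, rat replicate 3 was higher for Sparc, Bgn and Acta2. Of 3 measured T and NK cell genes, Cd247 and Cd28 were 1.44-fold and 1.19-fold higher with overlapping wells (other Cd28 probes 1.56-fold and 1.45-fold, adjusted p = 9.0e-05 and 0.00080), and Vpreb3, the only B cell gene measured, was 1.25-fold higher. For the probes chosen by brightness, leaving out at least 1 array ended each of these calls. Calls of Bst2 and Ctsk were also lost with median scaling (0.33 and 0.13). Of 3 dendritic genes Bst2 was 1.52-fold higher and Irf8 1.42-fold lower, and of 2 genes of the erythroid, platelet and mast cell list Pf4 was 1.38-fold lower. Against rat replicate 4 alone the log2 difference was -0.34 for Pf4 and 0.70 for Bst2, where the main values were -0.46 and 0.61. Adjusted over the list alone, 4 osteoclast, 3 neutrophil, 2 T and NK, 1 B, 2 dendritic and 1 stromal gene passed, and 1 of the erythroid, platelet and mast cell list. Reference genes had a median of 0.036, with 1 of 9 called over all genes and 0 adjusted over the list alone. Gusb differed by 0.25 (SE 0.082, adjusted p = 0.028), a call lost on leaving out any of 5 arrays though other Gusb probes rose by 0.35 and 0.38 (adjusted p = 0.0017 and 0.010), and Tfrc by 0.19 (SE 0.093, adjusted p = 0.11), which was -0.091 with median scaling.

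In all, camera with the preset correlation called 12 of 28 lists, 11 higher and 1 lower, while an estimated correlation left 1 and fry, which asks only whether a list's genes move 1 way on balance, called 25. Without rat replicate 4, 10 lists were called.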

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

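The response test for rat replicate 4, the Il1b test and the counts of splits were set before their results were seen; both brightness tests in their present form and both stromal tests were chosen afterwards.

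In 10 of 204 groups of 4 arrays, over the named genes and 5 array measures, the highest or lowest array lay far from the other 3. Chance flags about 1 in 20 groups, which comes to 10.2 here. In log2 intensity, human replicate 4 was high for Dusp1 (15.31 against a mean of 15.17 in the others), Nlrp3 (9.53 against 9.30) and Stip1 (11.70 against 11.64). Rat replicate 4 was low for Csf3r (9.80 against 10.19) and Il15 (11.62 against 11.80). Human replicate 1 was high for Ahsa1 (11.34 against 11.24), human replicate 2 low for Cd180 (12.19 against 12.28) and human replicate 3 high for Rpl19 (12.75 against 12.60). Rat replicate 1 was low for Nfatc1 (11.28 against 11.45) and rat replicate 3 high for Plk2 (7.78 against 7.51).

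Of 7809 genes 56.4% differed between the groups while 3 of the 4 rat arrays were brighter than every human array. For the counts, 1 of 35 splits of the 8 arrays, the real one, called as many genes and probes. The highest other split called 0 against 4401 genes and 6234 probes. With only 35 splits this cannot firmly exclude chance. Every other split also mixes the groups, so the group difference enters its spread and lowers its calls. Brightness as the cause argues for smaller differences against rat replicate 4, which is as dim as the human arrays. Over 4249 genes called from human replicates 3 and 4 against rat replicates 1 to 3 alone, the differences of human replicates 1 and 2 from rat replicate 4 followed with a slope of 0.86, and 92.0% had the same sign. Within the rat group, replicates 1 and 2 were dimmer than replicate 3 by 0.36 on the log2 scale, more than the human arrays were dimmer than the rat arrays (0.29), yet that contrast followed the response over all genes with a slope of 0.00013, and human replicate 4 minus 3, a gap of 0.26, with 0.074, so these values argue against brightness as the whole cause; the layout of the wells is not given in the sources used here.

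For lists the count of splits does not exclude chance either: 2 of 35 splits called at least as many lists, and the highest other split called 12, as did the real one. That split exchanged rat replicate 3 for human replicate 1. All 16 splits that keep 3 arrays of a group together called a list, while 1 of the 18 splits that mix the groups evenly did, with 1 list, so the splits that call many follow part of the real grouping.

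Rat replicate 4 lay apart from the other rat arrays, at -28.0 on the second principal component (8.26% of variance) against 12.7, 2.03 and 12.7, with 79 genes at least 2-fold from the mean of its group against 3 to 9 for the others. Array brightness is argued against: over those 79 genes, the difference between dimmer and brighter human arrays (replicates 2 and 4 minus 3) followed the deviation of rat replicate 4 with a slope of -0.013 (SE 0.039), where the ratio of the brightness gaps is 0.45. A partial human IAPP response in that well stays open, since its deviation followed the response across genes with r = 0.15, between the bounds set, and genes are not independent replicates. Within the groups, human replicate 4 minus 3 followed the response with r = 0.19, and rat replicates 1 and 2 minus 3 with r = 0.00052. An r of 0.15 is therefore not particular to rat replicate 4. The markers Col5a1, Sparc, Bgn and Acta2 were all highest in rat replicate 4 in normalised values, by a median of 1.19. Stromal cells that bring the other listed transcripts are argued against as their source: 0 of the other 10 stromal markers, Col1a1, Col1a2, Col3a1 and Dcn included, were detected in that well. These 10 are the markers that the filter on dim probes removed. They were thus picked for low detection, though detection in that well alone was still possible. Other kinds of stromal cell were not tested. Among the 21 genes at least 2-fold higher there were also Timp1 (1.42), Actg2 (1.34) and Serpinf1 (1.29), outside the list and named after their values were seen, and the source stays open. Nor do stromal cells account for the 58 genes at least 2-fold lower there, since dilution of macrophage transcripts would lower macrophage markers alike and these had a median of 0.13 and a lowest value of -0.27. Apart from these no biological explanation was tested.

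Il1b rose far less than Tnf and Il1a, and a scanner ceiling could compress a gene as bright as this. Of 179 genes at least as bright as Il1b in the rat arrays, itself included, 6 rose by at least 1.5-fold past the threshold, by 0.62 to 0.98 on the log2 scale. Those 6 were Lasp1, Cd9, Eif4a1, Atp6v1e1, Litaf and Cd14, of which Cd14 is named by the rule and the others after their values were seen. Among all 7809 genes 950 rose that far, a larger share, and Tnf and Il1a rose by 2.19 and 3.12. The 6 genes show that a rise could be read at that brightness, but do not by themselves exclude compression of a larger one. The raw Il1b signal ran from 19600 to 29976 on the human arrays, while the brightest probe of each array reached at least 66641. A larger Il1b rise thus had room below the ceiling, and these values argue against the ceiling as the limit for Il1b. Compression short of the ceiling was not tested. Whether rat IAPP raised Il1b stays open, as no untreated wells are among the samples.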

How the results depend on the processing

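Of the 95 called named genes, 78 kept direction and call in every alternative that was refitted per gene, which leaves out the other thresholds. Among these alternatives is rat replicate 4 alone as control, added after seeing the data, in which the lone array is assumed to vary like the human ones. Requiring a fold of at least 1.5 left 3126 probes and 2114 genes, and a test against a fold of 1.2 (treat) 3312 and 2364, both stricter by construction. Called lists fell to 1 with an estimated correlation and rose to 25 with fry. Values that keep the background shrink the changes of dim genes by construction: over the alternatives the log2 difference of Edn1 ran from 2.77 to 5.80, of Ccl2 from 2.66 to 5.57 and of Abcd2 from -2.71 to -0.74. Leaving out each array gave 5517 to 6727 probes, 3909 to 4758 genes and 10 to 12 lists.

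The TLR list turned in direction of its test with median scaling (median -0.42), with the mean over probes (-0.12) and against rat replicate 4 alone (-0.098), its median staying negative. So did the lysosome list with median scaling (-0.28) and the authors' values (0.11), the p53 list with median scaling (-0.50) and fry (-0.15), oxidative phosphorylation with the authors' values (0.060), and the LXR list with detection on all arrays (-0.18). Tfrc turned with median scaling (-0.091) and Tlr2 with the authors' values (0.076). Of these only Tlr2 was called in the main setting and only p53 with fry in the alternative. The cause was not tested.

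The replicate block gave 5891 probes, 4158 genes and 12 lists. Same-numbered arrays did not consistently deviate together (r = -0.11, -0.0061, 0.17 and -0.016 across probes), and 2 of 8 arrays correlated best with their own number. These values give no clear sign that the numbers pair the wells, but cannot exclude a weak pairing. A slide block was not run, since slides are not given. Signal over background limits dim genes: 11530 probes were detected on no array.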

Other observations

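Both tests here were chosen after the genes that prompted them had been seen, and each was run on list members not looked at before.

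Among genes that growth factor signalling controls through ERK, the named genes Egr1 and Ccnd1 rose with human IAPP. The phosphatase gene Dusp4 (3.25, SE 0.098) and the AP-1 gene Fosl1 (2.12, SE 0.15) rose, both named after their values were seen. These prompted the hypothesis that ERK output rose, so they do not test it. Among the 5 members not seen beforehand, the called ones were Spred1, Spred2 and Etv5, which rose, and the feedback phosphatase gene Dusp6, which fell by 0.76 (SE 0.11), with a median of 0.63, and the shift did not pass the test (camera p = 0.10, and p = 0.24 with an estimated correlation), so the hypothesis stays open.

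Genes that FoxO factors activate when growth signalling is low mostly went the other way among those first noticed. Sesn1 (-2.34, SE 0.17), Klhl24 (-2.04, SE 0.23), Mxd4 (-1.84, SE 0.13) and Fbxo32 (-1.68, SE 0.18) fell alongside Bmf, Trp53inp1 and Txnip, and Irs2 rose by 2.71 (SE 0.13), names again chosen after their values were seen. Of the other members already seen, Ypel3, Eef2k, Ulk1, Bcl2l11 and Map1lc3b fell. Klf2 rose by 0.43 (SE 0.092) and Gabarapl1 was not called. The hypothesis that FoxO targets fell as a set may not extend beyond these: the 7 members not seen beforehand had a median of 0.0036, with 3 lower and 1 higher (camera p = 0.73, and p = 0.78 with an estimated correlation), a set too small and mixed to decide.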
